A study of Mus musculus with 10 samples.

How the data were processed

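Gene expression was measured by RNA sequencing of the cerebral cortex of mice at postnatal day 8. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit. 5 libraries came from mice homozygous for a deletion of the element HAR.505 in the Rbfox1 locus and 5 from wild-type mice, and the series' design text states that the samples of each genotype were independent. The authors deposited a single table of whole-number counts per gene with Entrez gene identifiers. Reads were aligned with HISAT2 and counted with featureCounts against mm39, per the submitters' processing notes. The versions, the gene annotation, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of a transcript on the opposite strand cannot be told apart, and overlapping genes and near-identical copies such as the globin genes carry the same uncertainty.

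The table held 30935 genes, of which 7616 had no count in any library. Gene symbols were taken from a RefSeq table of the assembly GRCm38.p6, which differs from the authors' build and was used here for names and gene order, without coordinates. 30648 identifiers matched a symbol and carried 99.991% of the counts, and the 287 others kept their identifier. Library totals ran from 16479594 to 22391943 counts. Pairs of libraries of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom between 4.10 and 13.9 over genes with at least 20 counts in the pair, so each library was counted as 1 replicate.

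Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 15488 tested genes, libraries were scaled with TMM factors, and the genotypes were compared with the robust quasi-likelihood F test, with genotype as the sole term. P-values are two-sided and were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are log2 values of knockout against wild type, standard errors were derived from the F statistic, and intervals are 95% intervals. CPM values (deposited counts scaled to a common library total) were computed from the deposited counts with the TMM-scaled library totals. For Rbfox1, log2 CPM values were also compared with an exact two-sided permutation test over all 252 assignments of 5 of the 10 libraries.

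33 gene lists were written before the data were examined. They cover the Rbfox genes and their locus, neuronal functions, the cell types and neighbouring tissues a cortical dissection could hold, and RNA quality. 845 of the 863 list entries matched a gene in the table. Lists with at least 3 tested members were compared with camera in limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted over the 31 lists tested. The list of mitochondrially encoded genes had no member in the table, and the sex-linked list had too few members past the filter, so neither was tested. Camera with an estimated correlation and fry were run as alternatives. For each list, p-values were also adjusted over the list alone.

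The rule for named genes was fixed before the data were examined. It takes Rbfox1, Rbfox2 and Rbfox3, the 5 tested genes nearest to Rbfox1 on each side, the 12 genes with the smallest p among those past the threshold in each direction with predicted genes passed over, the 3 members with the smallest p of each list past the threshold, and any list member past the threshold over all genes. Genes named outside this rule, among them Ttr, Ppp1r1b, Enpp2, Cldn1 and Gm15564, were chosen after their values were seen, and 2 genes that the rule takes are not reported here but stay in all counts.

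The alternatives fixed before the data were examined were other normalizations, no filter or at least 50 counts in 5 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, an adjusted p under 0.1, a test against a fold of 1.2, each library left out in turn, a replicate block, a sex covariate from the counts, 1 surrogate variable from sva 3.50.0, and the neighbourhood of Rbfox1 with the sex-linked genes removed. 3 more were added after the data were seen: the mean log2 CPM of the choroid and ependymal list as a covariate, that of the striatal list, and a fit without knockout replicates 3, 5 and 6.

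The analysis was tested on simulated counts for the knockout against wild-type comparison, with 15350 genes in that step. In a single draw the test recovered 28.4% of genes changed by a fold of 1.2, 65.7% at 1.5 and 90.9% at 2. Genes of lowest expression were not among those changed. Over 10 draws, 98 of 1386 calls (7.07%) fell on unchanged genes, and a single draw with no gene changed gave 0 calls. Counts were drawn independently for each gene, so shifts shared by many genes of a library were not simulated. Gene totals do not resolve exons, so splicing was not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.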

Results

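The data set held 10 RNA sequencing libraries from the cerebral cortex of mice at postnatal day 8, an age at which cortical circuits are still maturing. 5 came from wild-type mice (replicates 2, 4, 5, 6 and 7) and 5 from mice homozygous for a deletion of HAR.505 (replicates 1, 3, 5, 6 and 8), called knockout here. Human accelerated regions are conserved sequences that gained many substitutions in the human lineage, and the series title places the elements studied among transcriptional enhancers of the RBFOX1 locus. The total counts of the wild-type libraries were 18893199, 18545880, 17251793, 22391943 and 19716321 in replicate order, and those of the knockout libraries 16809995, 18166712, 16479594, 17793346 and 17965177. The design asks which cortical genes, Rbfox1 first, differ in expression when the element is deleted.

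Rbfox1, which encodes a neuronal splicing regulator, was expressed at 224 ± 14.4 CPM (SD, n = 5) in wild-type and 215 ± 23.4 CPM (SD, n = 5) in knockout cortex. In replicate order the wild-type libraries held 205, 212, 233, 238 and 231 CPM, and the knockout libraries 229, 191, 209, 196 and 247 CPM. The log2 fold change was -0.06 with a standard error of 0.063, which did not pass the edgeR test (adjusted p = 0.879), and the exact permutation test of log2 CPM gave p = 0.421. The 95% interval of the fold change ran from 0.877 to 1.05, so an average change of Rbfox1 counts beyond these bounds lies outside it. The gene count does not cover a noncoding element and therefore does not check the genotype labels. Its relatives Rbfox2 (log2 fold change -0.04, SE 0.043) and Rbfox3 (log2 fold change 0.00, SE 0.052), which encode related splicing regulators, did not pass the test either. Among the 30 tested genes of the list of Rbfox splicing targets, 0 passed the edgeR test over all genes and 0 adjusted over the list alone, while 2 had an unadjusted p under 0.05. The median log2 fold change of the list was -0.0050 (camera adjusted p = 0.708).

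**Figure D1:**
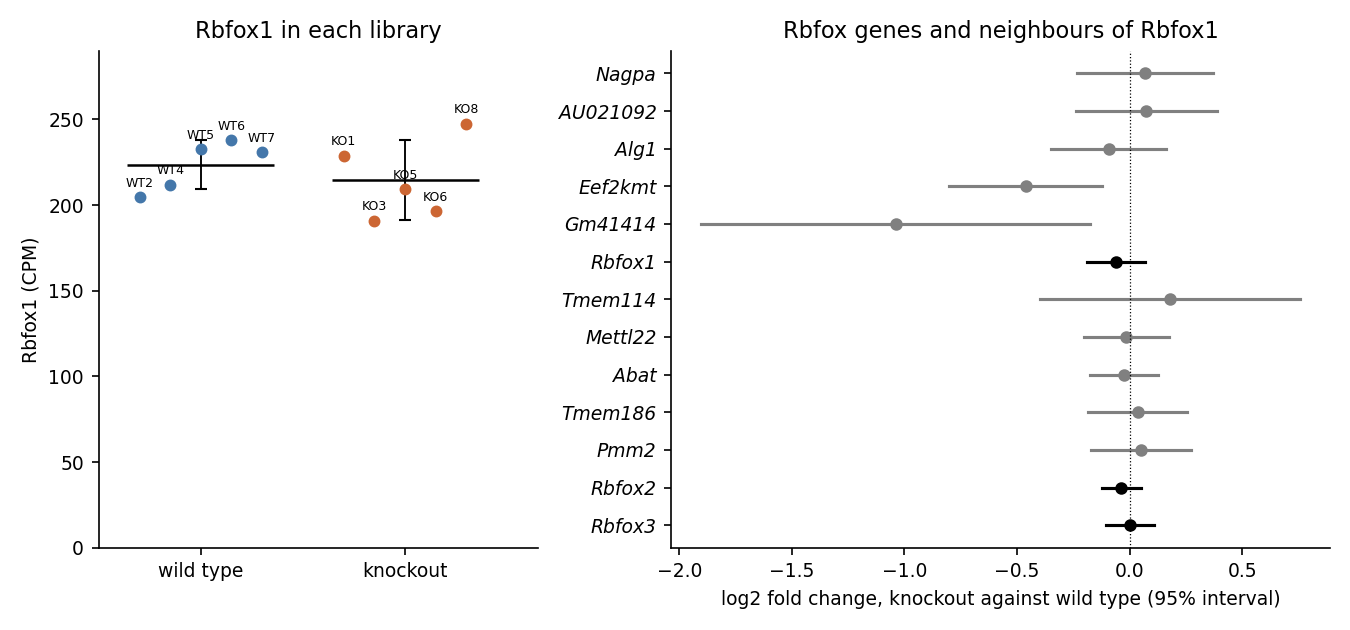
Rbfox1 in CPM in each library (left, dots; bars give the mean and SD of 5 libraries), and log2 fold changes of knockout against wild type with 95% intervals (right) for Rbfox1, the 5 tested genes on each side in GRCm38 gene order, Rbfox2 and Rbfox3. The Rbfox1 values of both genotypes overlap, between 205 and 238 CPM in wild type and between 191 and 247 CPM in knockout.

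Of the 10 tested neighbours of Rbfox1 in the gene order of GRCm38, 0 passed the test over all genes and 0 after adjustment over the neighbours alone, where 2 had an unadjusted edgeR p under 0.05. These were the 2 genes next to Rbfox1 on the side of lower coordinates. Gm41414, a predicted gene, stood at 1.07 ± 0.167 CPM in wild type and 0.513 ± 0.34 CPM in knockout (SD, n = 5 each), a log2 fold change of -1.04 (SE 0.42, adjusted p over the neighbours 0.0999), with counts too low for a precise fold. Eef2kmt, which encodes a methyltransferase of a translation elongation factor, stood at 6.18 and 4.47 CPM, a log2 fold change of -0.46 (SE 0.17, adjusted p over the neighbours 0.0936). The 8 others, among them the GABA transaminase gene Abat (-0.03, SE 0.072) and Tmem114 (0.18, SE 0.28), had log2 fold changes between -0.09 and 0.18.

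Across the transcriptome, the genes that fell in the knockout included the striatal genes Six3 and Penk and the choroid plexus genes Clic6 and Tmem72, and genes such as Dkk3, Nfix and Homer2 rose by small folds. 59 of 15488 tested genes passed the edgeR test, 29 higher and 30 lower in the knockout, and 1349 had an unadjusted p under 0.05. The median fold change was 1.21 among the higher genes and 0.559 among the lower genes. 12 genes were lower by more than 2-fold and 0 were higher by more than 2-fold. Except for Penk, these 12 stood at 6.48 CPM or below in wild type. At such low counts small folds are hard to detect, so the fold sizes of both groups are not directly comparable. In 47 of the 59 genes every knockout library lay on the same side of every wild-type library, and over all tested genes this held for 1.83%, against 0.794% by chance. The count of 59 depended on single libraries: it was 15, 21 and 17 without wild-type replicate 2, 4 or 5, and 17, 37 and 182 without knockout replicate 3, 6 or 8. It was 171 with no filter, 115 with DESeq2, 2 against a fold of 1.2, 28 with the sex covariate, 23 with 1 surrogate variable, and, with alternatives chosen after the data were seen, 0 with the choroid covariate (737 genes at an unadjusted edgeR p under 0.05), 1 with the striatal covariate (the predicted gene Gm15564, outside the naming rule) and 12 without knockout replicates 3, 5 and 6.

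**Figure D2:**
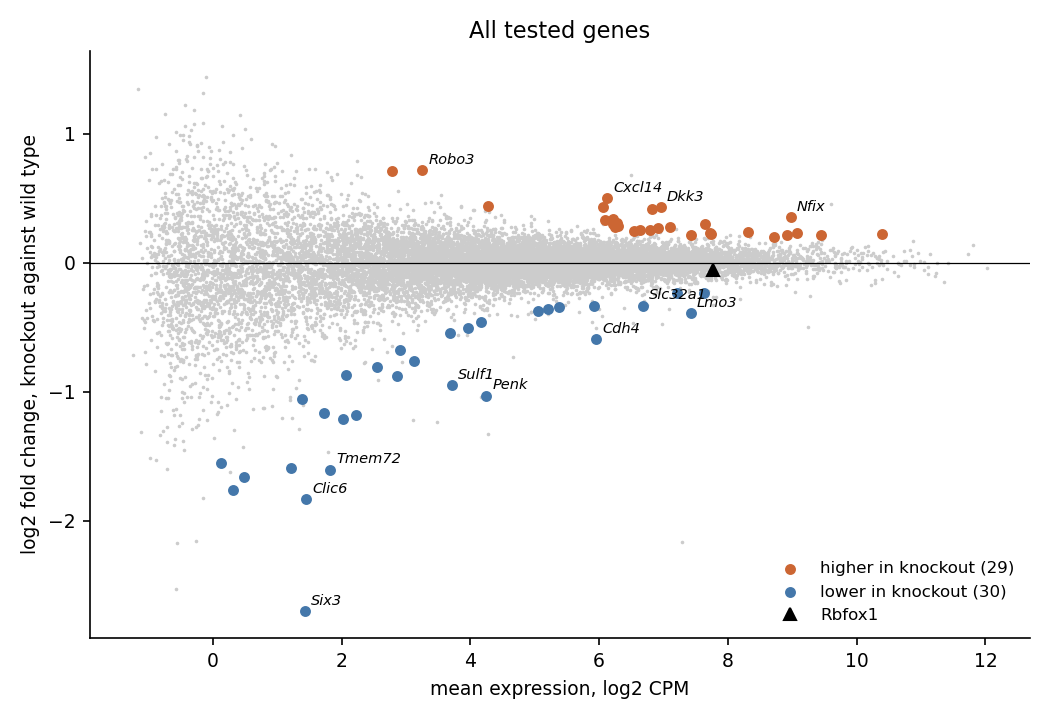
Log2 fold change of knockout against wild type (vertical axis) against mean log2 CPM (horizontal axis) for the 15488 tested genes (grey). Coloured dots mark the 29 genes higher and 30 genes lower in the knockout at an adjusted p under 0.05, and the triangle marks Rbfox1 at -0.06. Among the coloured dots the lowest is Six3 at -2.70, and the highest value among the higher genes is that of Robo3 at 0.72.

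Genes that rose in the knockout included Dkk3, which encodes a secreted protein of the Dickkopf family (log2 fold change 0.43, SE 0.053, adjusted p = 9.97e-05), and Nfix, a transcription factor of neural development (0.35, SE 0.050, adjusted p = 0.000456). Rxfp1, the relaxin receptor gene, rose by 0.43 (SE 0.068), and the chemokine gene Cxcl14 by 0.50 (SE 0.083). The axon guidance receptor gene Robo3 had the largest increase on the log2 scale of the 29, at 0.72 (SE 0.14), from 7.20 to 11.9 CPM. Nrsn1 (0.28), Dio2, which encodes the enzyme that activates thyroid hormone (0.33), the cyclin G gene Ccng1 (0.28) and the transcriptional cofactor gene Lmo4 (0.23) also rose. Dkk3, Nfix, Rxfp1 and Cxcl14 passed the test in each of the 10 fits that left out 1 library, as did 6 of the lower genes, and the 49 other genes each lost the call in at least 1 of these fits. 34 of the 59 were called in 5 or fewer of the 10 fits, among them Lmo4 (5).

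Synaptic genes were part of this higher group. In the list of 46 glutamatergic synapse genes, 3 rose and 1 fell over all genes, and 7 rose and 1 fell adjusted over the list alone. Homer2, which encodes a postsynaptic scaffold protein (0.27, SE 0.050), the metabotropic glutamate receptor gene Grm2 (0.33, SE 0.068) and the scaffold gene Dlg1 (0.26, SE 0.057) rose, and the kainate receptor gene Grik1 fell by 0.37 (SE 0.079). The list median was 0.06 and camera gave an adjusted p of 0.0176, with an adjusted p = 0.780 with an estimated correlation. Camera no longer called this list without wild-type replicate 4 (adjusted p = 0.0670, median 0.038) or knockout replicate 1 (0.0822, median 0.044) or 5 (0.138, median 0.041), or without knockout replicates 3, 5 and 6 (0.311, median 0.046). Nor did it with the choroid covariate (0.161, median 0.054) or the striatal covariate (0.844, median 0.0043). Of 24 GABAergic synapse genes, 1 rose and 1 fell, both over all genes and adjusted over the list alone, and the gene that fell was Slc32a1, the vesicular GABA transporter gene (log2 fold change -0.33, SE 0.061). Of 40 voltage-gated and related channel genes, Kcnj9 (0.24) and Scn2b (0.28) rose and the pacemaker channel gene Hcn4 fell by 0.35, and 5 rose and 1 fell adjusted over the list alone. Of the genes of these 3 lists, Scn2b was called in 2, Dlg1 in 3 and Kcnj9 in 4 of the 10 fits that left out 1 library. Camera called neither of the last 2 lists (adjusted p = 0.708 and 0.0696).

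Striatal genes were lower in the knockout libraries. Of 17 tested members of the striatal list, 2 fell over all genes, and 12 fell and 2 rose adjusted over the list alone. The median log2 fold change was -0.56, with a camera adjusted p of 8.19e-09 and an adjusted p = 0.506 with an estimated correlation. Six3, a homeobox transcription factor gene of striatal projection neurons, fell by 2.70 on the log2 scale (SE 0.36), from 4.67 ± 1.67 to 0.712 ± 0.491 CPM (SD, n = 5 each). Penk, which encodes the precursor of enkephalin, fell by 1.03 (SE 0.16), from 25.4 to 12.4 CPM. The dopamine receptor gene Drd2 had a log2 fold change of -0.77 (SE 0.20, adjusted p over all genes 0.0985). Without knockout replicates 3, 5 and 6 the list was still called, with a median of -0.38 (adjusted p = 0.0101), and with the choroid covariate the median was -0.27 (adjusted p = 0.0480).

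Choroid plexus and ependymal genes, markers of the tissue that secretes cerebrospinal fluid and of the lining of the ventricles, were also lower. Of 18 tested members 2 fell over all genes and 9 fell adjusted over the list alone, with a median log2 fold change of -0.91. The camera adjusted p was 4.12e-10, with an adjusted p = 0.354 with an estimated correlation. Clic6 fell by 1.83 (SE 0.32), from 4.24 to 1.19 CPM, and Tmem72 fell by 1.60 (SE 0.30), from 5.31 to 1.75 CPM. Folr1, a folate receptor gene, had a log2 fold change of -1.20 (SE 0.31, adjusted p over all genes 0.0960). Ttr, the abundant choroid plexus transcript for transthyretin and named here after its values were seen, stood at 213 to 278 CPM in the wild-type libraries. In the knockout libraries it stood at 200 CPM in replicate 1, 0.490 in replicate 5, 5.07 in replicate 6 and 80.6 in replicate 8. Replicate 3 had 0 Ttr counts, which allows up to 0.165 CPM as 3 counts of its total, from counting error alone. With that spread Ttr did not pass the test (log2 fold change -2.16, SE 1.15, adjusted p = 0.681). Without knockout replicates 3, 5 and 6 the list was still called, with a median of -0.45 (adjusted p = 4.63e-06). The median was -0.49 with the stricter filter (adjusted p = 0.000176) and -0.53 with the striatal covariate (adjusted p = 0.000839).

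**Figure D3:**
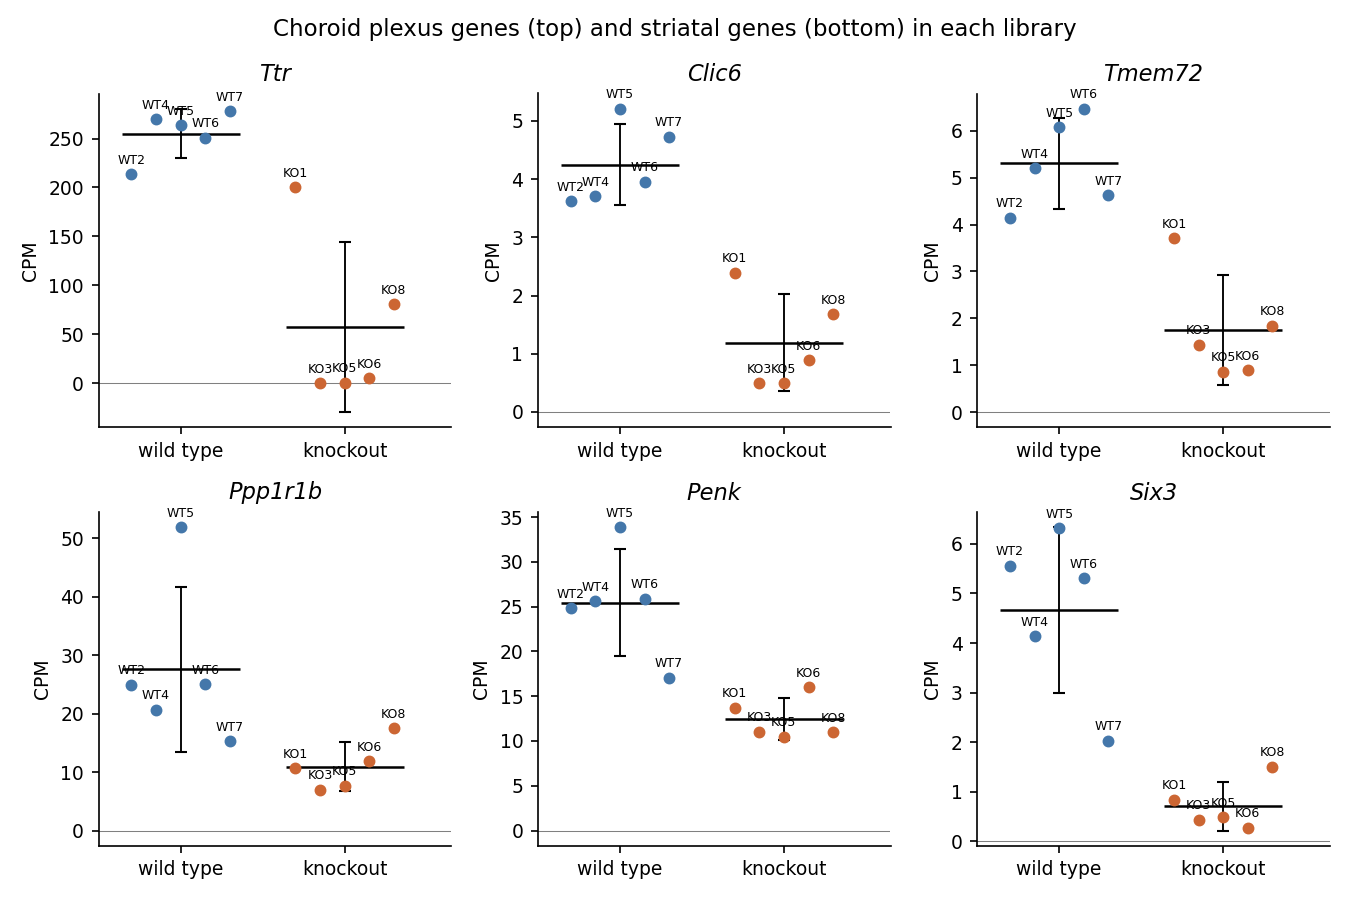
CPM in each library of the choroid plexus genes Ttr, Clic6 and Tmem72 (top) and the striatal genes Ppp1r1b, Penk and Six3 (bottom), of which Ttr and Ppp1r1b were chosen after their values were seen; dots are libraries and bars the mean and SD of 5. Ttr lies between 213 and 278 CPM in wild type and between 0 and 200 CPM in knockout, and every knockout library lies below every wild-type library for Clic6, Tmem72, Penk and Six3.

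Further genes that are not members of the striatal and choroid lists fell, but their fall is not shown to be separate from that of the striatal genes. Wild-type replicate 5 had the highest mean log2 CPM of the striatal list (4.33). It was also the highest wild-type library for Lmo3, Sulf1, Ankrd63, Vwa5b1, Ccdc187 and Cdh4, but not for Pappa2 or Egln3. Lmo3, a transcriptional cofactor gene, fell by 0.39 (SE 0.051, adjusted p = 0.000131), Sulf1, which encodes an enzyme that trims heparan sulfate, by 0.95 (SE 0.14), and Pappa2, a protease gene of insulin-like growth factor signalling, by 0.88 (SE 0.16). Ankrd63 fell by 1.18, Vwa5b1 by 1.21 and Ccdc187 by 1.59, each at under 7 CPM in wild type. Lmo3, Sulf1, Six3, Clic6, Pappa2 and Ankrd63 passed the test in each of the 10 fits that left out 1 library. The cell adhesion gene Cdh4 fell by 0.59 (SE 0.11) and the oxygen-sensing hydroxylase gene Egln3 by 0.50 (SE 0.12), while the activity-regulated transcription factor gene Nr4a3 rose by 0.30 (SE 0.064). They were the genes past the test over all genes in the lists of axon guidance and adhesion (54 tested, 3 higher and 6 lower adjusted over the list alone), stress and hypoxia (28 tested, 1 lower) and immediate-early genes (32 tested, 1 higher), which camera did not call. Cdh4 was called in 3, Egln3 in 2 and Nr4a3 in 5 of the 10 fits that left out 1 library.

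4 more lists passed camera, and 0 of their members passed the edgeR test over all genes. Erythroid genes were lower (7 tested, 2 at an unadjusted p under 0.05, median -0.33, 1 lower adjusted over the list alone, adjusted p = 0.00346, adjusted p = 0.506 with an estimated correlation). Alas2, the heme synthesis gene of red cells, had a log2 fold change of -0.63 (SE 0.22), and the globin genes Hbb-bt and Hbb-bs, near-identical copies whose reads are hard to assign, -0.50 and -0.36. Without knockout replicate 8, which had the highest mean of this list among the knockout libraries, the erythroid median was -0.51 (adjusted p = 1.11e-06), and with the choroid covariate it was -0.16 (adjusted p = 0.352). Oxidative phosphorylation genes had a median of 0.048 over 47 genes (adjusted p = 0.00516, adjusted p = 0.901 with an estimated correlation), with Ndufb5 at 0.15, Atp5a1 at 0.12 and Ndufa9 at 0.14. Astrocyte genes had a median of 0.079 over 20 genes (adjusted p = 0.00516, adjusted p = 0.780 with an estimated correlation), among them the glutamate transporter genes Slc1a2 (0.17) and Slc1a3 (0.15) and the glycolytic gene Aldoc (0.13). Microglia genes had a median of 0.095 over 20 genes (adjusted p = 0.0471, adjusted p = 0.850 with an estimated correlation), with P2ry13 at 0.34, Cx3cr1 at 0.12 and Trem2 at 0.23. Adjusted over the list alone, 0 genes of the last 3 lists passed the edgeR test, where 5, 3 and 1 had an unadjusted p under 0.05. Camera no longer called the oxidative phosphorylation list without wild-type replicate 6 (adjusted p = 0.189) or 7 (0.0701) or knockout replicate 3 (0.0768) or 6 (0.166, median 0.026), and without knockout replicate 5 the median was 0.082. It no longer called the astrocyte list without knockout replicate 6 (0.197, median 0.047). It no longer called the microglia list without wild-type replicate 2 (0.107, median 0.062), 5 (0.0542, median 0.0995) or 7 (0.227, median 0.068) or knockout replicate 3 (0.346, median 0.042) or 6 (0.359, median 0.054), nor with the sex covariate (0.134, median 0.060) or 1 surrogate variable (0.176, median 0.053). Without knockout replicates 3, 5 and 6 camera called none of these 4 lists (adjusted p between 0.206 and 0.797), the erythroid median was -0.11, and the astrocyte and microglia medians turned to -0.0057 and -0.038. With only knockout replicates 1 and 8 left in that fit, calls can also be lost through the smaller number of libraries.

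In total 7 of the 31 tested lists passed camera with the preset correlation and 0 with an estimated correlation, where 2, the choroid and striatal lists, had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance in 1 direction, 0 lists passed and 5 had an unadjusted p under 0.05. By its mixed test, of change in either direction, 8 passed. The median, the mean and the camera direction differed in sign for 7 lists, none of them called: the Rbfox1 neighbourhood, immediate-early genes, stress and hypoxia, deep-layer neurons, upper-layer neurons, mural and meningeal cells, and Rbfox splicing targets.

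**Figure D4:**
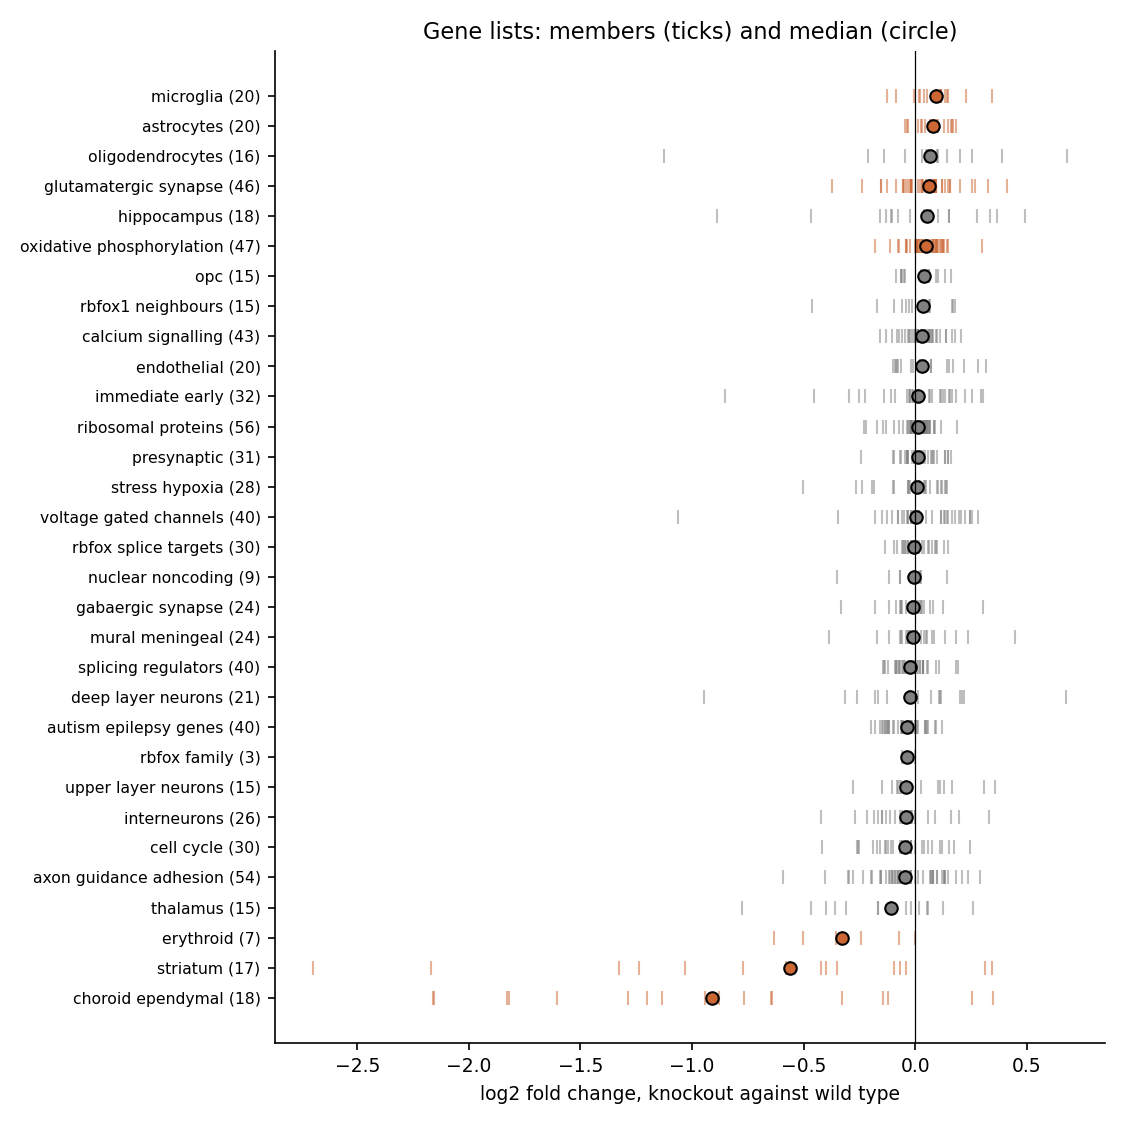
Log2 fold change of knockout against wild type for the members (ticks) and the median (circles) of the 31 tested gene lists, with the number of tested members in brackets. Orange marks the 7 lists past camera with the preset correlation, from the choroid and ependymal list at -0.91 and the striatal list at -0.56 to the microglia list at 0.095.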

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

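Of the tests in this part, the count of splits and the correlation of the higher genes with the striatal list were set before their results were seen; the others were chosen after. A value was singled out when the highest or lowest library of a genotype lay far from the other 4. This held in 12 of 136 groups of 5 libraries, and chance gives about 1 in 20; 11 of them are described. Knockout replicate 8 was highest for Hbb-bt (76.9 CPM), Hbb-bs (166 CPM) and the mean log2 CPM of the erythroid list (6.47), and lowest for Abat (158 CPM). Knockout replicate 3 was lowest for Ccng1 (79.6 CPM) and Nr4a3 (71.9 CPM). Knockout replicate 6 was highest for Gm41414, at 1.11 CPM against 0.299 to 0.428 in the other knockout libraries. Wild-type replicate 5 was lowest for Nfix (389 CPM) and highest for Ccdc187 (5.79 CPM), wild-type replicate 6 lowest for Eef2kmt (4.63 CPM), and wild-type replicate 4 highest for Alas2 (6.17 CPM).

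The number of genes between the genotypes was compared with other divisions of the same libraries. Of 100 drawn splits into 5 and 5, the real one included, 1 gave 59 genes or more, the real one, and the highest of the others gave 36. A random division of the libraries would therefore seldom give as many genes. This does not separate the genotype from anything else that differs between the 2 sets of mice.

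The choroid and ependymal genes were lower in the knockout. The data argue against sex of the animals, read from the counts, as the whole source: with the sex covariate the list median was -0.86, against -0.91 without it, and camera still called the list (adjusted p = 1.13e-09). Less choroid plexus carried along in the knockout dissections may account for it, since with genotype means removed Ttr and the mean of the other members moved together over the 10 libraries (Pearson r 0.925, permutation p = 0.0164, adjusted over 5 relations 0.0410; Spearman rho 0.842, p = 0.0369; r 0.811 without knockout replicates 1 and 3). In knockout replicate 3, with 0 Ttr counts, 2 of the 18 members, Enpp2 and Cldn1 (log2 fold changes -0.12 and 0.35), were at 10 CPM or above. In wild type, Ttr (255 CPM) and Enpp2 (108 CPM) alone averaged 10 CPM or above, so this count says little about the tissue. Of the 18 members, 0 belong to other lists. The mean log2 CPM of the list ran from 2.11 to 2.28 in wild type and from 0.0189 to 1.99 in knockout. The correlation therefore rests almost wholly on the knockout libraries. A change of the choroid plexus with the genotype would move its genes together as well and stays open, untested.

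The striatal genes were lower in the knockout. The data argue against sex here too, with a list median of -0.52 with the sex covariate against -0.56 without it (camera adjusted p = 8.30e-09). Less striatal tissue in the knockout dissections may account for it, since with genotype means removed Ppp1r1b followed the other members (Pearson r 0.852, permutation p = 0.00708, adjusted 0.0354; Spearman rho 0.721, p = 0.0354; r 0.482 without wild-type replicate 5 and knockout replicate 8, on which the relation largely rests). In knockout replicate 6, the library with the lowest list mean, 11 of the 17 members were at 10 CPM or above. Of the members that averaged 10 CPM or above in wild type, Adora2a alone (15.7 CPM) was not among these 11. Tac1 and Foxp1, 2 of the 17, belong to other lists. A difference in these neurons between the genotypes stays open, untested.

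The 29 genes higher in the knockout had a median log2 fold change of 0.279. A larger share of cortical tissue would raise cortical neuron genes alike. The 36 tested upper- and deep-layer genes did not rise as a group, with a median of -0.023 (95% interval -0.066 to 0.108, SD 0.251). However, the 29 genes were picked by their p in the same data, which inflates their median, and the layer genes include Sulf1, which was among the lower genes. The comparison therefore does not decide whether a larger cortical share contributed. A trend with the striatal share cannot be told apart from none with 10 libraries: with genotype means removed, the striatal list and the higher genes had a Pearson r of -0.484 (permutation p = 0.177, adjusted 0.283; Spearman rho -0.612, p = 0.0969; r -0.246 without wild-type replicate 5 and knockout replicate 8). A response of cortical neurons to the deletion stays open, untested.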

How the results depend on the processing

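The choroid and striatal covariates and the fit without knockout replicates 3, 5 and 6 were chosen after the data were seen. Rbfox1 stayed short of the threshold in every fit run, with log2 fold changes between -0.21 in the replicate block and 0.14 with either tissue covariate, and none of the 58 other named genes turned direction while past it. The count of 59 genes became 171 with no filter, 115 with DESeq2 (all 59 included), 108 at an adjusted p under 0.1, 2 against a fold of 1.2 (Six3 and Sulf1), 28 with the sex covariate and 23 with 1 surrogate variable. Leaving out 1 library gave 15 to 182 genes. RLE, library-size and upper-quartile scaling gave 57, 62 and 63, the stricter filter 53, non-robust dispersions 52 and limma-voom 45. It became 0 with the choroid covariate (737 at an unadjusted edgeR p under 0.05), 1 with the striatal covariate (Gm15564; 676 at an unadjusted p under 0.05) and 12, 6 of them shared, without the 3 libraries. With the covariates all 59 genes kept their direction. The median size of their log2 fold changes went from 0.389 to 0.339 and 0.323 and the median SE from 0.0764 to 0.121 and 0.124, as genotype accounts for 62.5% and 66.6% of the covariates' variance. The medians of the higher genes went from 0.279 to 0.267 and 0.239 and those of the lower genes from -0.839 to -0.522 and -0.607. The calls thus ended with larger errors and smaller fold changes, the more so for the lower genes. The 737 and 676 genes were each fewer than 1 in 20 of the 15488 tested genes, the share that chance gives. Because the 59 genes were picked in the same data, their kept direction does not show that a genotype effect remains.

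Of the lists, 4 passed with the choroid covariate, but of the 7 reported only the striatal list did. With the striatal covariate 7 passed, of which 2 were among those reported, the choroid and oxidative phosphorylation lists (the latter with a median of 0.079). With the choroid covariate the oxidative phosphorylation median was 0.0032 (camera adjusted p = 0.964). The astrocyte and microglia medians were 0.013 and 0.021 with the striatal covariate (camera adjusted p = 0.946 and 0.973). With an estimated correlation 0 passed. For the 7 reported lists the estimates ran from 0.138 (glutamatergic synapse) to 0.457 (striatal), against the preset 0.01, and a higher correlation raises the camera p. By directional fry, run on all 10 libraries, 0 passed. Camera with the preset correlation called 5 to 10 lists with 1 library left out, for which the cause was not tested. The choroid list turned to 0.022 with its own covariate and the striatal list to 0.021 with its own, as their construction forces. The astrocyte and microglia medians turned to -0.026 and -0.13 with the choroid covariate and to -0.0057 and -0.038 without the 3 libraries, and the erythroid median to -0.0049 with the striatal covariate; the cause was not tested.

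Only the numbers 5 and 6 occur in both genotypes. A replicate block on those 4 libraries gave 29 genes, 9 of them shared, and 4 lists, 3 of them shared (choroid, striatal and erythroid). Deviations of same-numbered libraries correlated at -0.030 and -0.057, which gave no sign that the numbers pair the libraries. With so few shared numbers, a pairing is not excluded. Totals of 16479594 to 22391943 counts limit precision most for genes near 1 CPM, such as Gm41414.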

Other observations

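The test of a local effect and the genes named in this part were chosen after the values were seen. The higher genes included Glul, the glutamine synthetase gene (log2 fold change 0.21, SE 0.045), Chn1, a signalling gene of axon guidance (0.24, SE 0.050), the dendritic gene Ddn (0.23, SE 0.051) and Klf9, a thyroid hormone-responsive transcription factor gene (0.21, SE 0.048). The lower genes included the kappa opioid receptor gene Oprk1 (-1.16, SE 0.25), Sp9, a transcription factor gene of striatal and inhibitory neurons (-0.54, SE 0.12), Zfhx4 (-0.67, SE 0.15) and Lin28b, a regulator of developmental timing (-0.87, SE 0.20). Of the 10 fits that left out 1 library, Glul was called in 5, Chn1 and Oprk1 in 4, and Ddn, Klf9, Sp9, Zfhx4 and Lin28b in 3.

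Most cell-type lists did not pass camera. Of 26 interneuron genes, 0 passed the edgeR test over all genes, where 6 had an unadjusted p under 0.05. Adjusted over the list alone, Vip was higher (0.33, SE 0.10) and Tac1 lower (-0.42, SE 0.13). Tac1 is also a member of the striatal list and was counted among the genes that fell there. The interneuron list's camera adjusted p was 0.179. Of 15 thalamic genes, 0 passed over all genes, where 3 had an unadjusted edgeR p under 0.05, and Zfhx3 was lower adjusted over the list alone (-0.77, SE 0.20). Of 21 deep-layer genes, 1 passed over all genes, Sulf1, and 4 were higher and 2 lower adjusted over the list alone, among them Tshz2 (0.68, SE 0.16), Fezf2 (0.22, SE 0.063) and Tbr1 (-0.18, SE 0.052), while of 15 upper-layer genes 0 passed either way and 4 had an unadjusted edgeR p under 0.05.

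Sex was read from the counts. Wild-type replicate 7 and knockout replicates 3 and 6 held 3458, 3340 and 3160 counts over 4 Y-linked genes and at most 5 Xist counts. The other 7 libraries held at most 8 Y-linked counts and at least 12147 Xist counts.

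Gm41414 and Eef2kmt, side by side next to Rbfox1, were both lower in the knockout without passing the test, and a local effect of the deletion is a candidate explanation. Over 15434 pairs of adjacent tested genes, 0.317% had a mean signed root F as low, but the pair was picked for being low. Allowing for that choice, 5.25% of 15254 neighbourhoods of 5 tested genes on each side held a pair as far from 0 in either direction, so a local effect cannot be told apart from chance here.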
